A study of Mus musculus with 2 samples.

How the data were processed

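Genomic regions carrying histone H3 monomethylated at lysine 4 (H3K4me1) were measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos at embryonic day 14.5. There was 1 group of 2 biological replicates, each made from a separate pool of embryos (24 in replicate 1 and 34 in replicate 2), with library fragments in the range of 300 to 500 bp. Groups and replicate numbers were taken from the labels. No other tissue or age entered, and no control library was analysed here, so nothing was tested between groups of samples.

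The deposited data were 4 peak lists on the mouse build mm10 (GRCm38), per the labels and the text files that accompany them. The first and second hold the peaks of each replicate, the third the peaks called on both replicates together (the pooled list), and the fourth the replicated peaks, which were derived from the other 3 lists. The list of replicate 1 was made from its alignments and 2 further files of unstated role, and that of replicate 2 from its alignments and 1 further file. The aligner, the peak caller and their versions are not given in the sources used here. Each peak in the deposited lists has a fold enrichment, which is a ratio of signal to a background that is not described. The deposited lists also give each peak's −log10 p and −log10 q. These values are the authors' own. They were used to describe, rank or filter peaks within a list and to set strength beside strength in shared regions. For the closing section, −log10 p was also compared between the replicate lists at equal fold enrichment, and fold enrichment between chromosome X and the autosomes within the pooled list. Read numbers are not part of the peak lists, so the depth of each library is unknown and no interval that needs it is given.

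Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the computations and matplotlib 3.10.9 for the plots. Peaks were placed on the GENCODE M21 annotation of the same build, with chromosomes 1 to 19, X and Y. A gene's transcription start site (TSS) was the 5′ end of its annotated span. After 27 repeated symbols had been left out, 21911 protein-coding genes remained. A promoter was called CpG-rich when the observed over expected CpG ratio within 500 bp of the TSS was at least 0.6, which gave 10067 CpG-rich and 11844 CpG-poor promoters. Coordinates are 1-based.

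Overlap of the replicates was the share of one list's peaks that met a peak of the other by at least 1 bp. It was set beside 100 circular shifts of one list along each chromosome (seed 7), and positions relative to genes were set beside 100 shifts of the replicated list. Position was assigned by the peak midpoint as within 1 kb of a TSS, 1 to 10 kb from one, further away but in a gene, or further away and intergenic. At TSSs, the percent of genes with a peak covering the base was taken at the TSS and at a distance of 1.5 kb on both sides. For gene lists, the percent of the window from 50 kb upstream to 50 kb downstream of each member's TSS that lay in replicated peaks was averaged over members. That mean was compared by a two-sided permutation test with 10000 random lists of as many genes, matched on up to 10 classes of local gene density (1000 random lists for the receptor families and other very large families). The classes were deciles of the number of protein-coding TSSs in the window, and genes with equal numbers shared a class. The smallest p that 10000 lists can give is 0.0001. The p-values were adjusted by Benjamini-Hochberg over the 23 lists, with a threshold of 0.05. They compare genes within these libraries and say nothing about the spread between animals. Dense loci were found by joining replicated peaks across gaps of up to 12.5 kb. Values over the replicates are the mean ± SD of the 2 single-replicate lists (n = 2).

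The 23 lists, the tests and most alternatives were fixed before the data were examined. The lists covered forebrain patterning factors, the cortical excitatory and ventral GABAergic lineages, radial glia, pan-neuronal genes, Cajal-Retzius cells, choroid plexus, oligodendrocytes, astrocytes, microglia, endothelium, erythroid cells, midbrain and hindbrain factors, Hox genes, heart, skeletal muscle, liver, pancreas and intestine, epidermis, germline, housekeeping genes, and olfactory and vomeronasal receptors. One liver symbol was matched through a synonym (Tf to Trf), Hprt1 stood for a gene already listed (Hprt), and the symbol Loricrin in the epidermal list was not matched. The rule for naming genes allowed the 4 members of each list with the highest window coverage and the 2 with the lowest by the mean of both replicates. Genome-wide it allowed the 20 highest genes with 1 per 100 kb locus, the 10 longest joined regions and the 5 replicated peaks with the highest fold enrichment. Receptor families were given as counts only.

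The list test was tested on simulated data in which lists of 20 of the 21911 genes were given known changes in coverage. Of 100 lists with no change, 6 were called at an unadjusted p under 0.05. The simulated lists were drawn at random from all genes, so this rate does not cover lists of clustered genes with overlapping windows. Of 100 lists for each size of change, 51 were called at a planted fold of 1.5, 79 at 2 and 100 at 3. Alternatives were stricter −log10 q minima (2 and 5), other overlaps, windows, flanks and gaps, other matching of random lists, other TSS sets, the pooled list, equal numbers of peaks and each replicate alone. Wherever a gene body is named as a window, it is the annotated gene together with 5 kb on each side. Alternatives chosen after seeing the data were autosomal genes only, matching also on CpG class, and only those replicated peaks that overlap a peak in both replicates, and for gene families also leaving out members of the fixed lists. For the closing section, 25 gene families defined by their symbols were tested in the same way with a separate adjustment, and chromosome X was compared with autosomal bins of 100 kb matched on repeat share, GC content and number of TSSs.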

Results

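H3K4me1 marks enhancers and the flanks of promoters, and its distribution was mapped in the mouse forebrain at embryonic day 14.5, when cortical neurons are being produced. The data were the peak lists of 2 biological replicates, which were pools of 24 and 34 embryos, together with a pooled list and a replicated list made from both. Replicate 1 had 127392 peaks covering 49.6 Mb and replicate 2 had 81016 peaks covering 32.3 Mb. The pooled list had 123868 peaks over 61.1 Mb. The replicated list had 82314 peaks over 50.2 Mb, which was 1.91% of chromosomes 1 to 19 and X. The lists included weakly supported peaks. The lowest −log10 q was 0.454 in replicate 1, 0.223 in replicate 2 and 0.461 in the replicated list. A −log10 q of at least 2 was reached by 66.8%, 45.6% and 82.6% of the peaks in these 3 lists. Median peak width was 293 bp in replicate 1, 306 bp in replicate 2 and 471 bp in the replicated list, with median fold enrichments of 3.07, 3.50 and 3.34. Sequencing depth is unknown from these lists, and there was no second group, so the comparisons are between replicates, between genomic positions and between groups of genes.

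The first comparison asked how far the replicates marked the same regions. The windows of 100 kb centred on protein-coding TSSs ranked alike in both, with a Spearman correlation of 0.95 across 21911 genes, which are not independent replicates. The gene windows were covered to 2.92% on average in replicate 1 and 1.98% in replicate 2. Peak by peak, 58500 of the replicate 1 peaks (45.9%) overlapped a replicate 2 peak, and 59095 of the replicate 2 peaks (72.9%) overlapped a replicate 1 peak. After circular shifts the shares were 2.37% ± 0.09 and 3.72% ± 0.13 (SD over 100 shifts), so the observed overlaps were 19.3-fold and 19.6-fold higher, and 0 of 100 shifts reached either. Shared bases made up 20.2 of 61.8 Mb covered in any of the 2 lists (32.6%). Strength in the shared regions agreed loosely: across 50105 of them the Spearman correlation of fold enrichment was 0.33. Only regions called in both lists entered this value, so it cannot be ranked against the agreement in position. When a reciprocal overlap of 50% was required, the shares fell to 24.1% and 37.9%.

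Peaks found in replicate 1 alone numbered 68892 (54.1%). They were weaker and narrower than its shared peaks, with a median fold enrichment of 2.97 against 3.44 and a median width of 248 bp against 404 bp. The 21921 peaks found in replicate 2 alone (27.1%) had a median fold enrichment of 3.29 against 3.62 for shared peaks. Of the replicate-specific peaks, 63.2% in replicate 1 and 77.5% in replicate 2 overlapped a peak of the pooled list. With equal numbers of peaks per list, the number specific to replicate 1 was 35625 and the number specific to replicate 2 was 32387.

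The replicated list was a subset of the pooled list, since all 82314 of its entries were identical to pooled entries. Of these peaks 85.6% overlapped a replicate 1 peak, 69.8% a replicate 2 peak and 60.6% a peak of each, while 4237 (5.15%) overlapped neither. The peaks overlapping both replicates were stronger than the rest, with a median fold enrichment of 3.71 against 3.0. Of the 41554 pooled peaks left out of the replicated list, 549 (1.32%) overlapped peaks of both replicates. The rule by which replicated peaks were chosen is not given in the sources used here, so a replicated peak is not necessarily one listed in each replicate.

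Relative to genes, H3K4me1 peaks were concentrated at and near TSSs while most lay far from them. Of the replicated peaks, 10.6% had their midpoint within 1 kb of a protein-coding TSS (9.23% ± 0.85 in the single replicates, SD, n = 2), against 1.63% after circular shifts, a 6.52-fold difference. A further 21.9% (21.8% ± 1.07, n = 2) lay 1 to 10 kb from a TSS, 1.74-fold more than after shifts. Peaks inside genes over 10 kb from a TSS made up 40.2% (41.4% ± 0.99, n = 2), 1.23-fold more than after shifts. Intergenic peaks over 10 kb from a TSS made up 27.3% (27.5% ± 0.93, n = 2), against 53.2% after shifts. In each class 0 of 100 shifts lay as far from the mean of the shifts. The median distance to a TSS was 36.3 kb, and 7.54% of the midpoints fell in exons against 3.8% after shifts. With the TSSs of all annotated genes in place of protein-coding ones, the intergenic share was 17.4% and the median distance 11.9 kb.

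CpG-rich promoters, which include most housekeeping and many developmental genes, had few peaks on the TSS itself and many on both sides. At the TSS 3.2% ± 1.48 (SD, n = 2) of the 10067 CpG-rich promoters were covered. At 1 kb downstream the share was 32.0% ± 5.49 and at 1 kb upstream 15% ± 3.49 (n = 2 each). CpG-poor promoters lacked this dip. At the TSS 5.63% ± 1.82 of the 11844 CpG-poor promoters were covered, with 6.22% ± 1.43 at 1 kb downstream and 2.14% ± 0.69 at 1 kb upstream (n = 2 each). The mean of both flanks at 1.5 kb minus the TSS was 13.4 ± 1.63 percentage points for CpG-rich promoters and -2.54 ± 0.89 for CpG-poor ones (n = 2 each). These differences had the same sign in both replicates, and no test was made on the 2 values. Over all 21911 promoters the replicated list gave 6.14 points, but with flanks at 3 kb the difference was -1.23 points.

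**Figure D1:**
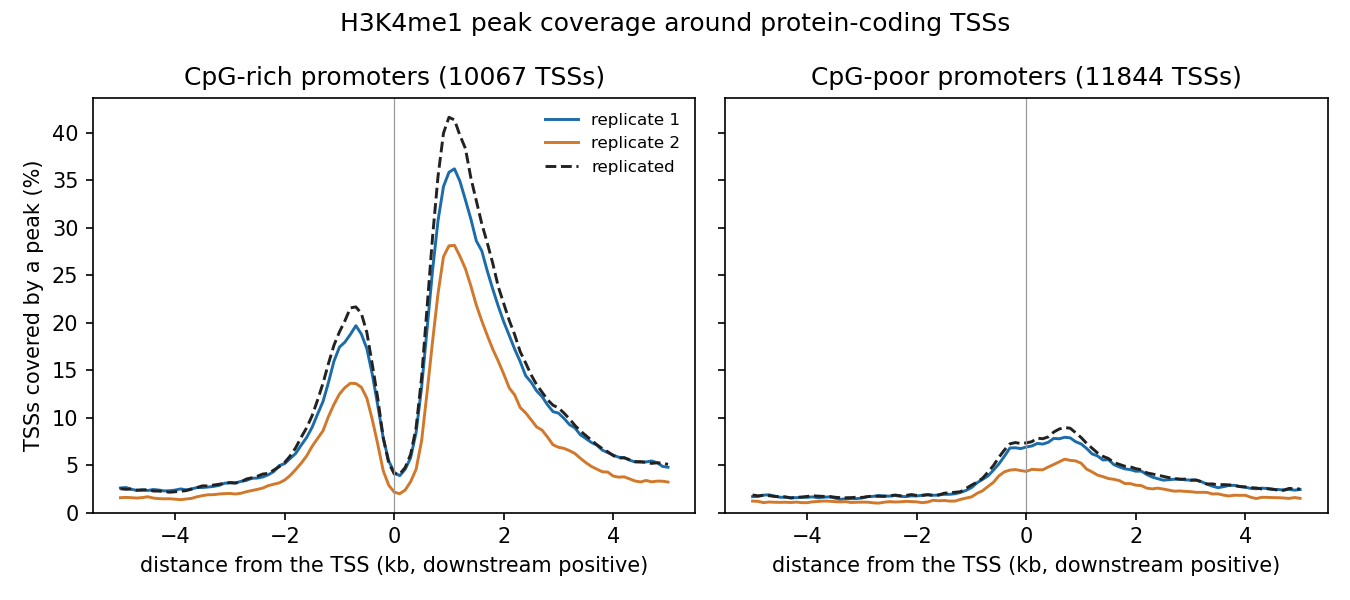
Percent of protein-coding TSSs covered by an H3K4me1 peak (vertical axis) against distance from the TSS in kb (horizontal axis, downstream positive), for CpG-rich and CpG-poor promoters, with 1 line for each replicate and a dashed line for the replicated list. In CpG-rich promoters the replicated list reached 41.7% at 1 kb downstream and 4.08% at the TSS, and both replicates showed the dip.

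Genes of the cortical excitatory lineage and of radial glia had the densest H3K4me1 around their TSSs among the 23 gene lists, and which of them led depended on the window. The mean coverage of the windows of the cortical excitatory genes was 10.3% in the replicated list (8.19% ± 1.74 in the single replicates, SD, n = 2), against 2.55% in matched random lists, a 4.05-fold excess. Of the 24 members, 11 lay above the 90th percentile of genes and 2 below the median. Bcl11b, a transcription factor of corticospinal neurons, was covered to 28.1% ± 4.34 and Bcl11a to 24.7% ± 2.32 (n = 2 each). The neuronal differentiation factors Neurod2 and Nhlh1 were covered to 17.0% ± 1.92 and 15.2% ± 1.72 (n = 2 each). The lowest members were Slc17a6, which encodes a vesicular glutamate transporter, at 1.11% ± 0.67, and Rorb, a layer 4 nuclear receptor, at 1.91% ± 1.31 (n = 2 each).

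Radial glia and progenitor genes were covered to 8.83%, 3.52-fold above matched lists (7.12% ± 1.57, n = 2), and 11 of 20 members lay above the 90th percentile. With a window of 10 kb on each side they lay at 16.1% and the cortical excitatory genes at 15.9%. Over the gene body with 5 kb on each side the 2 lists lay at 18.3% and 17.5%. Notch1, a receptor that keeps progenitors undifferentiated, reached 23.3% ± 3.55 and Nes, which encodes the intermediate filament nestin, 13.1% ± 2.17 (n = 2 each). Fgfr3 stood at 12.3% ± 4.56 and Sox2 at 12% ± 2.02 (n = 2 each), while the X-linked Sox3 was at 0.587% ± 0.086 and Tnc at 0.736% ± 0.190 (n = 2 each). Some lists share members and are not independent. Fgfr3 was also among the 4 highest astrocyte genes, and Sox2 among the 4 highest forebrain patterning factors. Forebrain patterning factors were covered to 6.92%, 2.83-fold above matched lists (5.41% ± 1.92, n = 2). Sox1, Pax6 and Emx1, which specify neural and cortical territory, stood at 13.3% ± 5.07, 9.26% ± 2.70 and 9.01% ± 2.49 (n = 2 each). Rax, a factor of the early eye field, and Hesx1, of the anterior forebrain and pituitary, were lowest at 1.18% ± 0.61 and 1.49% ± 0.15 (n = 2 each). By the two-sided permutation test the Benjamini-Hochberg adjusted p was 0.000767 for the first 2 lists and 0.0023 for the patterning factors. The unadjusted p of 0.0001 behind the lower value is the smallest the random lists can give. With a −log10 q minimum of 5 the patterning factors were 1.64-fold above matched lists, with an adjusted p of 0.346 by permutation.

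Ventral GABAergic genes were covered to 4.29%, 1.76-fold above matched lists (3.52% ± 1.1, n = 2), with an adjusted permutation p of 0.068 that misses the threshold. Meis2 stood at 14.4% ± 3.16, Prox1 at 9.77% ± 0.08, the GABA transporter gene Slc32a1 at 7.68% ± 2.79 and Dlx1 at 5.83% ± 1.01 (n = 2 each). Nkx2-1, which specifies the medial ganglionic eminence, had no peak in its window in either replicate, and Lhx8 was at 0.409% ± 0.303 (n = 2). Without replicate 2 the fold was 1.79 with an adjusted permutation p of 0.043. On the replicated list windows of 10 kb and 100 kb and the gene body gave adjusted permutation p-values of 0.0236, 0.0434 and 0.0138. Random lists matched on gene length gave 1.43-fold (adjusted permutation p = 0.220) and unmatched ones 1.42-fold (0.208). A −log10 q minimum of 5 gave 1.35-fold (0.675). The call thus rests on the choice of list and of window, and the size of the excess also on the matching and the −log10 q minimum. Other neural lists also lay above matched lists without passing the test on the replicated list. Astrocyte genes were at 2.01-fold (adjusted permutation p = 0.0774), Cajal-Retzius genes at 1.97-fold and pan-neuronal genes at 1.66-fold (both 0.0872), and oligodendrocyte genes at 1.65-fold (0.136). On the pooled list pan-neuronal genes (1.76-fold, adjusted permutation p = 0.0446) and Cajal-Retzius genes (2.16-fold, 0.0488) passed, while with a −log10 q minimum of 5 Cajal-Retzius genes lay at 1.04-fold and oligodendrocyte genes at 0.974-fold. Among their members, Rbfox3, which encodes the neuronal protein NeuN, stood at 12% ± 3.12, Cacna2d2 at 10% ± 4.47, Olig1 at 9.29% ± 3.29 and Olig2 at 7.02% ± 2.78 (n = 2 each). Reln, the secreted product of Cajal-Retzius cells, was at 0.635% ± 0.467 and Scg3 at 0.174% ± 0.246 (n = 2 each).

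Markers of other cells and organs did not pass the test in the window of 50 kb on each side of the TSS, though some did in other windows. Microglia genes lay at 1.36-fold (adjusted permutation p = 0.326), housekeeping genes at 1.25-fold (0.371), skeletal muscle at 1.22-fold (0.655), cardiac genes at 1.14-fold (0.817), midbrain and hindbrain factors at 1.11-fold and erythroid genes at 1.10-fold (both 0.820). Germline genes lay at 1.03-fold and choroid plexus genes at 0.951-fold (both 0.914), endothelial genes at 0.762-fold (0.648), pancreas and intestine genes at 0.758-fold (0.655), liver genes at 0.477-fold (0.133) and epidermal genes at 0.291-fold (0.0742). With a window of 10 kb on each side germline genes lay at 0.121-fold (0.0319) and housekeeping genes at 1.71-fold (0.0214). Over the gene body housekeeping genes lay at 1.81-fold (0.0156) and midbrain and hindbrain factors at 2.28-fold (0.00986), with 100 kb on each side microglia genes lay at 2.07-fold (0.00287), and on the pooled list epidermal genes lay at 0.310-fold (0.0488). Closer to the genes microglia genes lay below matched lists without passing, at 0.668-fold with 10 kb on each side and 0.503-fold over the gene body, as did erythroid genes at 0.493-fold and 0.546-fold. The windows of single members were still high. That of Nfe2, a blood transcription factor, was covered to 14% ± 1.16, Cpa1 to 11.7% ± 1.43, Figla to 10.6% ± 3.05 and Hexb, which encodes a lysosomal enzyme, to 7.85% ± 1.71 (n = 2 each). Nfe2, Cpa1 and Figla had no replicated peak within 2 kb of their TSSs, and their windows held 4, 2 and 2 protein-coding TSSs. Hexb had such a peak. These limits were not confined to non-neural genes. Bcl11a, Meis2 and Slc32a1 also had no replicated peak within 2 kb, whereas Bcl11b, Neurod2, Nhlh1, Notch1 and Nes had one. The windows of Nes, Nhlh1 and Neurod2 held 5, 4 and 3 protein-coding TSSs, and those of Bcl11b and Notch1 held 1 each. The microglial gene Trem2, the globin gene Hbb-bt, the liver gene Cps1 and the keratin gene Krt5 had no peak in their windows in either replicate. A peak in the replicated list lay within 2 kb of the TSS in 22 of 24 housekeeping genes and in 1 of 14 epidermal genes.

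Hox genes, which pattern the hindbrain, spinal cord and trunk, were covered to 1.31%, against 4.71% in matched lists, which is 0.278-fold (0.989% ± 0.564, n = 2). None of the 39 members lay above the 90th percentile and 11 had no replicated peak in the window. The highest, Hoxd8, stood at 2.71% ± 1.16, and Hoxc12 and Hoxc13 at 0 in both replicates (n = 2). The adjusted permutation p was 0.000767. Hox genes lie in 4 clusters, and with each cluster counted as 1 locus the fold was 0.282 with an adjusted permutation p of 0.221. Random lists matched on gene length in place of gene density gave 0.432-fold (adjusted permutation p = 0.0318), and unmatched ones 0.429-fold (0.0249). Olfactory receptor genes, which are expressed in the nose, were covered to 0.136%, 0.0365-fold of matched lists, and 1006 of 1134 had no replicated peak in the window. Vomeronasal receptor genes were covered to 0.0649%, 0.0246-fold of matched lists, and 311 of 330 had none. The adjusted permutation p was 0.00383 for both receptor families. Counted as loci, olfactory receptors lay at 0.133-fold and vomeronasal receptors at 0.0133-fold, and both passed.

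**Figure D2:**
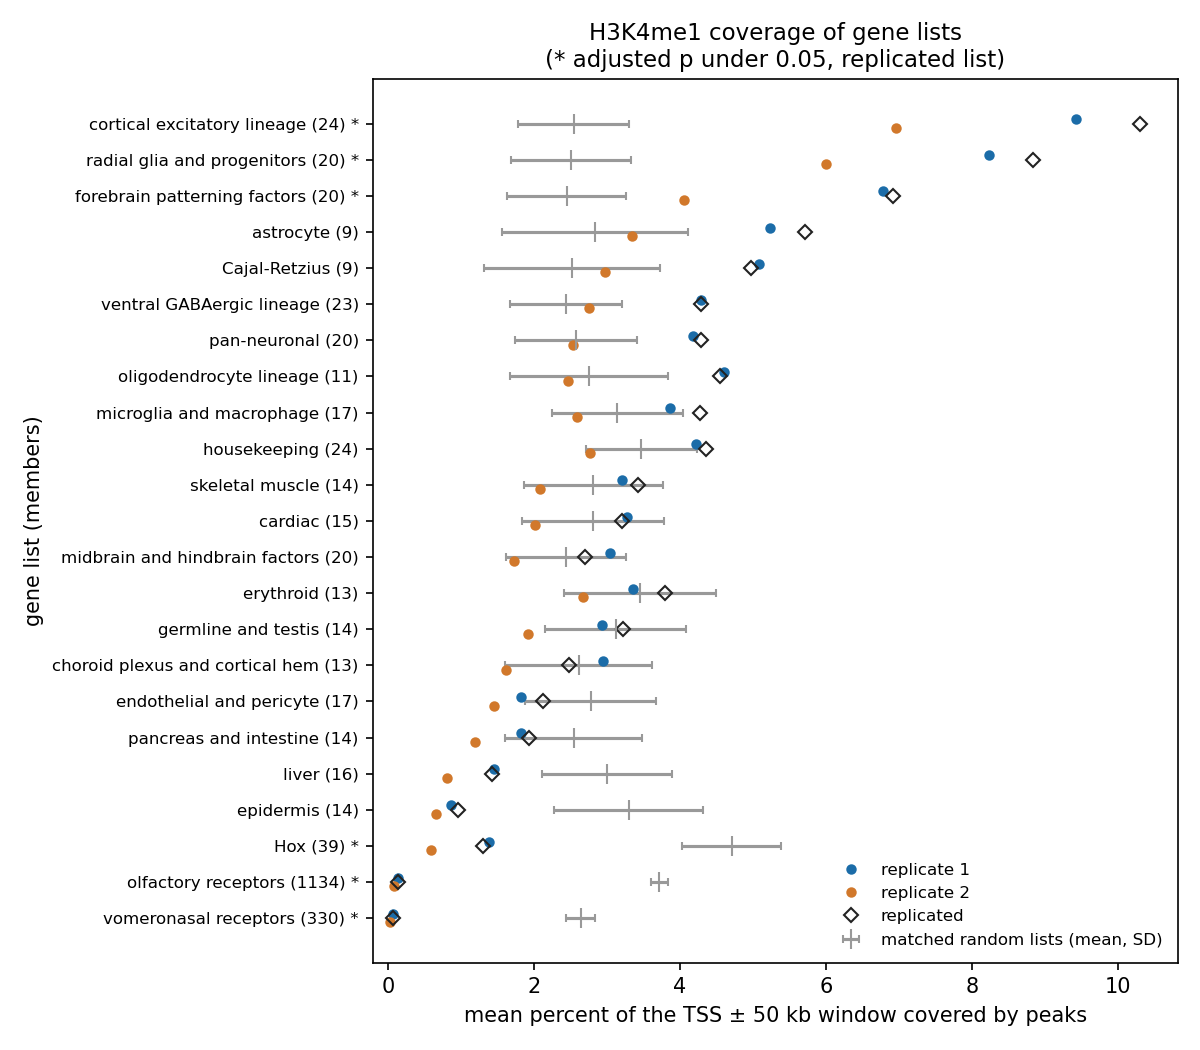
Mean percent of the window of 50 kb on each side of the TSS that was covered by H3K4me1 peaks (horizontal axis) in each of the 23 gene lists (vertical axis, members in brackets), with filled circles for each replicate, open diamonds for the replicated list and grey bars for the mean and SD of matched random lists scored on the replicated list. The cortical excitatory list lies at 10.3% and the radial glia list at 8.83%, and both replicates of these lists lie above the grey bars; the single-replicate circles have a lower general level than the replicated list.

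Across all protein-coding genes the mean window coverage was 3.05% and the median 1.89%, and 5244 genes (23.9%) had none. A replicated peak lay within 2 kb of the TSS in 11682 genes (53.3%). The highest windows genome-wide were those of Pipox at 39.9% ± 2.06, Ncor2, a nuclear receptor corepressor, at 40.4% ± 2.55, Flrt1 at 36.7% ± 2.17 and G430095P16Rik at 32.9% ± 6.26 (n = 2 each), ranked by the replicated list. Tcf20, Foxo6 and Lrp8, a reelin receptor, followed at 32.0% ± 3.32, 32.3% ± 3.99 and 31.2% ± 4.99 (n = 2 each). The remaining 13 of the 20 highest were Stra6, Bahcc1, Tle3, Bcl11b, Zfp608, Map4k4, Bcl11a, Zmiz1, Rara, Ssbp3, Notch2, Ccdc85c and Cxxc5, with replicated coverage from 34.1% down to 28.0%.

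At Bcl11b (chromosome 12, 107910403 to 108003602, minus strand, mm10) 29 replicated peaks met the window of 50 kb on each side of the TSS, with 41 peaks in replicate 1 and 39 in replicate 2. They lay mostly in the gene, and the strongest replicated peak within 100 kb of the TSS spanned 107959670 to 107962464 in an intron, with a fold enrichment of 6.73.

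**Figure D3:**
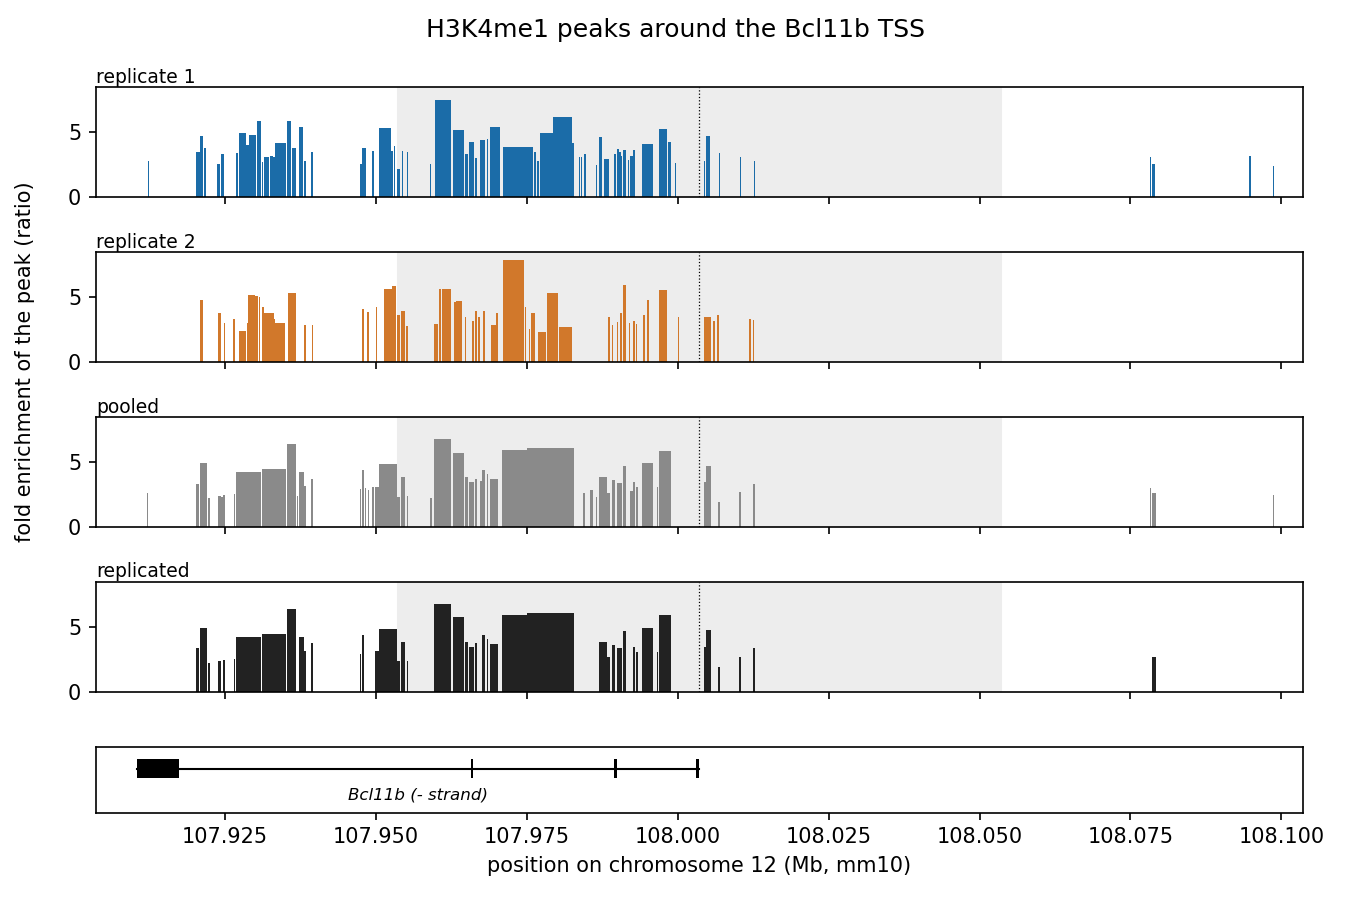
Fold enrichment of H3K4me1 peaks (vertical axes, ratio) against position on chromosome 12 in Mb (horizontal axis, mm10) within 100 kb of the Bcl11b TSS, which is the dotted line, with the scored window of 50 kb on each side in grey and the exons of Bcl11b as boxes. Bars are single peaks of replicate 1, replicate 2, the pooled list and the replicated list, and the replicated list holds 46 of the 60 pooled peaks shown.

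The strongest replicated peaks lay mostly in introns. The highest, with a fold enrichment of 9.87, was in an intron of Ccdc85c (chromosome 12, 108244106 to 108246346) and had 8.58 ± 0.15 in the single replicates (n = 2). Introns of Fyn, which encodes a tyrosine kinase (chromosome 10, 39484095 to 39485764), Tcf20 (chromosome 15, 82936035 to 82939210) and Parvb (chromosome 15, 84298720 to 84304000) held peaks of 9.11, 8.99 and 8.97. The fifth, at 8.74, was intergenic and 73.9 kb from the TSS of Irf2bp2 (chromosome 8, 126666750 to 126668984), and its strength differed between replicates, at 4.43 in replicate 1 and 10.9 in replicate 2.

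Joining replicated peaks across short gaps gave 28510 regions, of which 392 were 50 kb or longer. The longest was 354 kb at Msi2, which encodes an RNA-binding protein of neural progenitors (chromosome 11, 88375610 to 88729780), with 150 peaks covering 41.0% of it. Gse1 and the overlapping model Gm20388 followed with 316 kb on chromosome 8 (120251272 to 120567285), then the adhesion gene Cadm1 with 258 kb, Pbx1 with 213 kb, Celf4 with 190.4 kb, Casz1 with 189.8 kb, Auts2 with 186 kb and Fyn with 177 kb. Regions holding Nfix and Lyl1 (174 kb) and Cacna2d2 (169 kb) completed the 10 longest, with 10 and 12 protein-coding genes in them. With a gap of 5 kb 22 regions reached 50 kb, with a gap of 25 kb 1955 did, and of the 10 longest regions 4 overlapped these 10 in either case. With replicate 1 alone, 723 regions reached 50 kb and 3 of its 10 longest overlapped these 10, and with replicate 2 alone 304 and 5.

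Called H3K4me1 peaks covered far less of chromosome X than of the autosomes. The replicated list covered 0.101% of X and between 1.52% (chromosome 16) and 3.13% (chromosome 11) of the autosomes, which together stood at 2.03%, 20.2-fold higher than X. The ratio was 15.5 in replicate 1 and 18.8 in replicate 2. X carried 378 replicated peaks and Y carried 0. With a −log10 q minimum of 5 the ratio was 68.3.

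**Figure D4:**
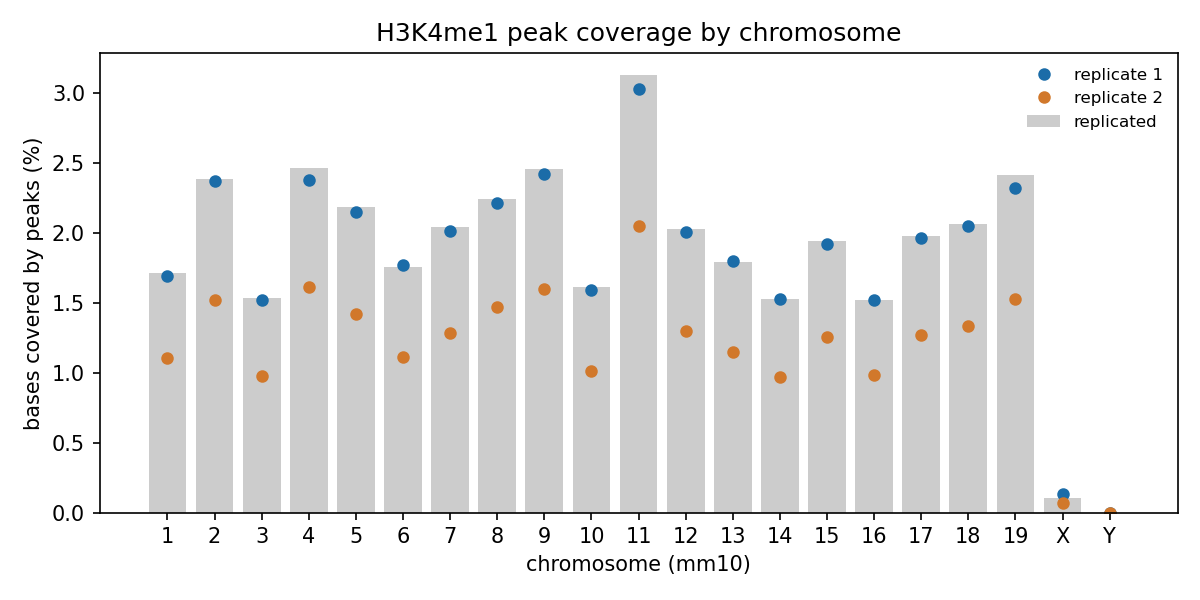
Percent of the bases of each chromosome (horizontal axis) covered by H3K4me1 peaks (vertical axis), with bars for the replicated list and points for each replicate. Autosomes stand between 1.52% and 3.13%, X at 0.101% and Y at 0.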

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

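Alternatives for the gene lists chosen after seeing the data were autosomal genes only, matching also on CpG class, and only replicated peaks that overlap both replicates; the rest were set before the data were examined. None of these 3 changed a gene list's call, and the third gave an autosome to X ratio of 26.8. Every alternative set beforehand was run. No paired analysis was possible because the series holds a single group. Where a value moved, the cause was not tested unless the alternative's own construction, such as fewer peaks, shows it. The unknown depth limits how far the weaker peaks of replicate 2 can be compared.

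With a −log10 q minimum of 2, replicate 2 kept 36950 peaks over 19.2 Mb and the pooled list 79936 peaks, and the overlap was 34.3% of replicate 1 peaks and 76.3% of replicate 2 peaks. With a minimum of 5, the lists kept 13346, 3651, 20980 and 20897 peaks over 10.6, 3.36, 20.7 and 20.7 Mb (replicate 1, replicate 2, pooled and replicated). The overlap was then 19.1% and 67.1%, and 17.7% of bases were shared. At this minimum 27.8% of peaks lay 1 to 10 kb from a TSS, 37.9% in a gene further away and 23.3% in intergenic sequence further away. The flank minus TSS difference was 5.0 points for all, 11.3 for CpG-rich and -0.359 for CpG-poor promoters. The forebrain patterning factors lost their call (1.64-fold), and the autosome to X ratio was 68.3. Merging peaks within 500 bp left 81983 pooled peaks.

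With equal numbers of peaks the overlap was 56.0% of replicate 1 and 60.0% of replicate 2 peaks, the correlation of fold enrichment was 0.316 and replicate 1 had 35625 specific peaks. The correlation of −log10 q was 0.377. When 50% of the peak had to be covered the overlap was 33.8% and 59.9%, and with 50% reciprocal overlap 24.1% and 37.9%. When 50% of the replicated peak had to be covered, 76.8% met replicate 1, 56.5% replicate 2 and 42.4% both.

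With the TSSs of all annotated genes, 14.3% of peaks lay within 1 kb, 32.4% within 1 to 10 kb, 35.9% in a gene further away and 17.4% in intergenic sequence. Flanks at 1 kb gave differences of 11, 26.3 and -1.94 points for all, CpG-rich and CpG-poor promoters. Flanks at 3 kb gave -1.23, 3.01 and -4.84 points, which turned the sign for all promoters.

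In the gene lists, the permutation test called ventral GABAergic genes higher with a 10 kb window (1.94-fold), a 100 kb window (1.71), the gene body (2.21) and the pooled list (1.82). Housekeeping genes were called higher with the 10 kb window (1.71) and the gene body (1.81), microglia genes with the 100 kb window (2.07), and midbrain and hindbrain factors with the gene body (2.28). Pan-neuronal (1.76), Cajal-Retzius (2.16) and epidermal genes (0.310) were called with the pooled list. Germline genes turned to 0.121-fold with the 10 kb window and were called lower. Microglia genes went the other way with the 10 kb window (0.668) and the gene body (0.503), without a call. So did erythroid genes (0.493 and 0.546), and choroid plexus genes lay at 1.87-fold over the gene body. With a −log10 q minimum of 5, oligodendrocyte genes (0.974) and midbrain and hindbrain factors (0.911) fell below matched lists and Cajal-Retzius genes came to 1.04-fold. Cardiac, skeletal muscle, endothelial, choroid plexus, germline, and midbrain and hindbrain lists also crossed 1-fold under some alternatives without a call, apart from those named. Hox genes lost their call when counted as loci (0.282). The number of lists called higher was 5 with the 10 kb and the 100 kb window, and 6 with the gene body and with the pooled list. The cortical excitatory, radial glia and both receptor lists were called in the same direction under every alternative run.

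Joining gaps of up to 5 kb gave 22 regions of 50 kb or longer and a longest one of 177 kb, and gaps of up to 25 kb gave 1955 and 745 kb.

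Without one replicate (either left out), the share within 1 kb of a TSS ranged from 8.63% to 9.83% and that in a gene over 10 kb away from 40.7% to 42.1%. The flank minus TSS difference ranged from 4.60 to 4.98 points for all, from 12.3 to 14.6 for CpG-rich and from -3.16 to -1.91 for CpG-poor promoters. The fold for ventral GABAergic genes ranged from 1.75 to 1.79 and was called without replicate 2. Regions of 50 kb or longer ranged from 304 to 723.

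For the 142 named genes, the window coverage under 7 alternatives differed from the replicated list's by less than the SD between replicates in 404 values. It was higher by more than that in 215 values and lower in 375, of which 113 came from the −log10 q minimum of 5 and 100 from leaving out replicate 1.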

Other observations

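The gene families below were chosen after the fixed lists had been tested, and of the explanations weighed, the comparison of −log10 p at equal fold enrichment was chosen only after the result was seen; the other tests were set before their values were seen. Families of axon guidance molecules had dense H3K4me1 around their TSSs. The windows of 22 ephrins and Eph receptors were covered to 8.79%, 2.94-fold above matched random lists (6.53% ± 1.57, SD, n = 2), with 9 members above the 90th percentile of genes. Epha4 stood at 20.4% ± 2.22 and Ephb2 at 18.9% ± 4.42 (n = 2 each). The 29 semaphorins and plexins were covered to 8.14%, 2.6-fold above matched lists (6.54% ± 1.31, n = 2), with 12 members above the 90th percentile, such as Sema3b at 17.7% ± 2.38 and Plxna2 at 15.6% ± 2.12 (n = 2 each). The adjusted permutation p over 25 families was 0.000417 for both. The 4 nuclear factor I genes were covered to 18.1%, 6.05-fold above matched lists, led by Nfix at 24.7% ± 5.6 (n = 2). Notch receptors and ligands lay at 3.92-fold, with Notch2 at 21.1% ± 3.6 (n = 2), and both families had an adjusted permutation p of 0.0005. SOX genes lay at 2.35-fold (0.00208) and nuclear receptors at 2.00-fold (0.000909), the latter led by Rara at 25.5% ± 1.39 (n = 2). All named genes in this paragraph were chosen after their values were seen. Each of these 6 families also passed when matched on CpG class and when counted as loci. Members of 4 of them had been in the fixed lists, so these families in part retest genes already seen to be high: 2 nuclear factor I genes, 2 Notch genes, 8 SOX genes and 2 nuclear receptors. Without those members, a test added after the results were seen, the folds were 6.70, 3.02, 2.06 and 2.02, with adjusted permutation p-values of 0.00075, 0.00205, 0.0218 and 0.00075. Notch2 and Rara stayed in this test although they were among the 20 highest windows genome-wide. It therefore does not free the families of genes already seen to be high, and its nuclear factor I value rests on 2 genes.

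Other families lay lower. The 19 GABA-A receptor genes were covered to 0.312%, 0.129-fold of matched lists (0.321% ± 0.187, SD, n = 2), 8 of them had no replicated peak in the window and none lay above the 90th percentile (adjusted permutation p = 0.0294). Matched on CpG class as well the p was 0.0428, but counted as 14 loci it was 0.088 at a fold of 0.146. Ionotropic glutamate receptors lay at 1.57-fold and did not pass (0.0903), and the difference between the receptor families was not tested. Clustered protocadherins were covered to 1.41%, 0.294-fold (0.000417), and 43 of 56 had none, but they form 3 loci and with these the fold was 0.383 and the p 0.297. Cytochrome P450 genes lay at 0.320-fold and passed under both checks (0.0175 with CpG class, 0.0275 over 36 loci). Keratins (0.239-fold), beta-defensins (0.0730-fold), bitter taste receptors (0.111-fold) and UDP-glucuronosyltransferases (0.0101-fold) passed with CpG class and missed the threshold as loci, where their folds were 0.215, 0.102, 0.406 and 0 over 4, 7, 9 and 3 loci. Forkhead genes (1.53-fold), chemokines (0.449-fold) and interleukins (0.514-fold) passed only without matching on CpG class, and as loci forkhead genes kept their call (1.62-fold, 0.0164) while chemokines (0.584-fold, 0.206) and interleukins (0.574-fold, 0.132) lost theirs. The histone clusters (1.52-fold) lost their call as 6 loci (1.4-fold, 0.297). The POU domain, Zic, LIM homeobox, Wnt and Frizzled, potassium channel, collagen and zinc finger families did not pass, with folds from 0.896 to 1.94, except that the zinc finger genes (0.896-fold) were called lower when matched on CpG class (0.856-fold, 0.0269) and lay at 1.06-fold as 217 loci (0.524).

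Chromosome X was covered 20.2-fold less than the autosomes, and its 100 kb bins had more repeats (median 45.7% against 31.7%), less GC (38.9% against 41.4%) and fewer TSSs (0.574 against 0.866 per bin). Autosomal bins matched on these 3 properties were still covered 7.07 times as much as the X bins, against a range of 0.773 to 1.21 when each autosome was compared with the others, which argues against sequence and gene content as the whole explanation. At the rank of 1 pooled peak per Mb the fold enrichment was 3.34 on X and 5.40 ± 0.23 on the autosomes (SD over 19 autosomes), a ratio of 0.618. Whether fewer X copies in pools of both sexes contribute stays open, because the background of the fold enrichment is not described: a background that shares the copy number would bring the ratio near 1, and one that does not would leave it at 0.5 or more, and no biological explanation was tested.

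Replicate 1 had 127392 peaks and replicate 2 had 81016. The replicate 1 peaks were split into 10 equal classes by strength. The strongest class was found in replicate 2 in 88.5% of cases and the weakest in 24.5%, a difference of 64.0 percentage points. Most of the strongest peaks were thus not specific to 1 pool of embryos. For weaker peaks the difference cannot decide, because regions weakly marked in only 1 pool would give the same gradient. Of the replicate 2 peaks with a −log10 q of at least 5, 98.5% were found in the unfiltered list of replicate 1. Of the 13346 such peaks of replicate 1, 88% were found in the unfiltered list of replicate 2. With the minimum set on both lists the shares were 67.1% and 19.1%. At equal fold enrichment the median −log10 p was between 1.21 and 1.37 times higher in replicate 1 in each of 7 bins, which is consistent with lower statistical power, for example fewer reads, in replicate 2. Read numbers were not analysed here, and the further input files differed between the lists, so the source of that power stays open.

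Around CpG-rich TSSs the coverage at 1 kb was 2.15 ± 0.14 times as high downstream as upstream (SD, n = 2). Where no other annotated gene started within 5 kb (5343 TSSs) the ratio was 3.35 in replicate 1 and 4.24 in replicate 2, which argues against neighbouring TSSs as its source. Where all annotated transcripts of a gene started within 200 bp (2453 TSSs) the ratio was 2.26 and 2.29. This argues against annotated downstream TSSs as its source. Starts that are missing from the annotation could not be seen by this restriction. Both restrictions together (1269 TSSs) gave 4.06 ± 0.72 (n = 2). No biological explanation was tested.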
